A study of Mus musculus with 6 samples.

How the data were processed

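Liver RNA was measured on 6 Affymetrix mouse exon arrays, 3 of SRSF3HKO and 3 of WT liver. Per the labels' protocols, livers were taken from untreated mice at 1 month of age, total RNA was isolated with RNeasy kits and checked on a Bioanalyzer, and labelled by the standard Affymetrix procedure. Per the submitters' processing notes, the authors summarised core exon probe sets with PLIER in Affymetrix Expression Console, and the deposited values are linear PLIER intensities; the versions and the background step are not stated. Genotype comes from the labels, and replicate numbers follow the order of the samples. All 229581 probe sets and all 6 arrays were used.

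Probe sets were joined to genes through the annotation supplied with the series. Of the probe sets, 208397 had 1 gene, 3965 had several and 17219 had none. Only the first kind entered the gene-level, exon usage and list tests, whereas the test of single probe sets used all kinds. The annotation gave 16299 symbols, of which 14132 were current, 2124 were updated to the current symbol and 43 were kept as listed, for 16277 genes in all. Intensities were transformed as log2(value + 16), so that changes of dim genes are understated. The level of a gene was the median over its probe sets. Genes and probe sets were tested where their mean over the 6 arrays lay above the 90th percentile of 1047 olfactory, vomeronasal and taste receptor genes, which liver is not known to express. This floor was 5.35 for genes and 5.67 for probe sets on the log2 scale, and it left 11691 genes and 155942 probe sets. Where a group mean lay below the floor, the fold of a gene is given as a lower bound computed from the floor.

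SRSF3HKO was compared with WT with limma 3.58.1 (moderated t-test with a mean-variance trend) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The number of arrays limits the precision. Exon usage, the change of a probe set relative to the other probe sets of its gene, was tested with limma's diffSplice in 131600 probe sets of 10403 genes with at least 3 tested probe sets, with Simes adjustment per gene. A per-array splicing index (probe set minus gene level) tested with limma was the second test of exon usage. Data were read with data.table version 1.17.8, and figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

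Gene lists were fixed before the data were examined and hold 628 genes, 555 of them with probe sets of 1 gene; the others were not analysed here. They cover the SR protein family, other splicing factors, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation and ketogenesis, glucose and glycogen metabolism, the growth hormone and IGF axis, bile acid synthesis and transport and xenobiotic metabolism. They also cover mature hepatocyte proteins, hepatocyte transcription factors, fetal liver and liver tumour genes, cell cycle, unfolded protein response, NRF2 antioxidant genes, p53 target genes, acute phase and inflammation, iron handling, extracellular matrix and epithelial-mesenchymal transition. The rest are male-biased, female-biased and sex-chromosome genes, markers of cholangiocytes, macrophages, lymphocytes, neutrophils, endothelial cells, stellate cells, erythroid cells and hepatocytes, pancreatic and adipose genes, and genes fixed for splicing. Lists with at least 5 tested genes, apart from the genes fixed for splicing, were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with limma's fry. Members are counted with the adjustment over all genes and with the adjustment over the list alone.

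The genes named in the report follow a rule set before the data were examined. They are Srsf3, the 12 highest rises and 12 largest falls among called genes with at least 2 probe sets, a proper symbol and no overlap between the groups, and up to 4 called members per list with the lowest adjusted p. They also include the SR family, the genes fixed for splicing, and the 12 probe sets of different genes with the lowest adjusted p for exon usage. Some further called members of the lists and the probe sets called by both tests of exon usage were named after their values were seen.

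The alternatives set beforehand were pseudocounts of 1 and 64, quantile normalization, median centring, mean or median polish over probe sets, no filter or a filter at the median, eBayes without trend, robust eBayes, array weights, an adjusted p under 0.01, a change of at least 1.5-fold, at least 5 probe sets, genes changed under 1.5-fold, the splicing index, other list tests, and leaving out each array in turn. The Y-linked signal as a covariate was added after the arrays had been seen. Each gene, probe set and list test was also repeated on the 10 splits of the 6 arrays into 3 and 3.

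The pipeline was tested on simulated data of 2 groups of 3 arrays, with 100 changed genes or probe sets at each size. With spreads shrunk across genes, limma recovered 47% of genes with a log2 change of 1 and 99% at 2, and 6.40% of its calls were false. For exon usage diffSplice recovered 31% and 97% with 33.7% false calls, the splicing index 4% and 72% with 11.6%, and calls made by both 3% and 70% with 2.70%. With the measured spreads, limma recovered 30% and 91% of genes with 6.20% false, diffSplice 32% and 95% with 59.0%, the index 4% and 64% with 10.5%, and both together 3% and 61% with 3.00%. Positions of probe sets and exon structures were not analysed here, so no called probe set is tied to an exon.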

Results

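SRSF3 is a splicing factor of the SR protein family, and the knockout examined here removed it from hepatocytes, the main cell type of the liver. Liver RNA of 1-month-old untreated mice was measured on Affymetrix mouse exon arrays, which carry several probe sets per gene. The series holds 6 arrays, 3 from hepatocyte-specific Srsf3 knockout mice (SRSF3HKO) and 3 from wild-type controls (WT) described as age-matched littermates. The comparison asks which liver transcripts, and which parts of transcripts, differ when hepatocytes lack SRSF3. Median intensity over 229581 probe sets lay between 75.3 and 89.6 on the 6 arrays, and no further measure of depth exists for arrays, whose number limits the precision. Across genes, WT arrays correlated with one another at Pearson's r of 0.979 to 0.984, SRSF3HKO arrays at 0.940 to 0.965, and arrays of different genotype at 0.906 to 0.949. These are correlations across genes, which are not independent replicates. The median SD of a gene's log2 value was 0.187 in WT and 0.291 in SRSF3HKO. The labels name 3 knockout mice but do not say whether each WT array comes from a separate mouse, so p-values measure only the spread between these samples. The Y-linked gene Eif2s3y had log2 values of 8.62 in WT replicate 1, 8.36 in WT replicate 2 and 8.99 in SRSF3HKO replicate 3. In WT replicate 3 and SRSF3HKO replicates 1 and 2 its values were 4.18, 4.16 and 4.17, below the detection floor of 5.35, so arrays with and without Y-linked signal stood in both groups. The 2 measured sex-chromosome genes had a median log2 change of -0.89 with none called, also adjusted over the list alone. Every log2 change below is SRSF3HKO minus WT on the log2(intensity + 16) scale, which understates the change of dim genes, with its SE and 3 arrays per group. Adjusted p-values of genes and probe sets are limma's.

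The target gene Srsf3 did not move as one unit across its 14 probe sets. In the 13 that were bright enough to test, 6 rose by a log2 change of 1.25 to 1.68, and 3 others had lower means in SRSF3HKO. Probe set 4625796 had an intensity of 1569 ± 340 in WT and 804 ± 399 in SRSF3HKO (SD, n = 3), a log2 change of -1.03 ± 0.33 (limma adjusted p = 0.0842). Probe set 5430400 went from 1589 ± 348 to 822 ± 355 and probe set 5531798 from 1102 ± 332 to 594 ± 217 (limma adjusted p = 0.0767 and 0.111). Probe set 4630152, with the highest rise, went from 529 ± 165 to 1734 ± 521 (log2 change 1.68 ± 0.28, limma adjusted p = 0.010). Relative to the other probe sets of the gene, the 3 dimmed probe sets were used less in SRSF3HKO by limma's diffSplice (log2 usage change -1.72, -1.68 and -1.56, adjusted p = 0.00939, 0.0120 and 0.0249). The geometric mean intensity of these 3 probe sets over that of the 6 risen ones was 1.54, 1.69 and 1.5 in the WT arrays and 0.446, 0.203 and 0.304 in the SRSF3HKO arrays. The probe sets of this ratio were chosen after their values were seen, so it was not tested. At gene level the median over probe sets gave log2 values of 9.79, 9.24 and 9.35 in WT and 10.30, 9.10 and 9.78 in SRSF3HKO, a log2 change of 0.26 ± 0.31 (limma adjusted p = 0.625). This small difference turned to -0.02 without SRSF3HKO replicate 1 and was 0.81 with median polish over probe sets (limma adjusted p = 0.0781). The labels do not say which part of the gene was deleted and the positions of the probe sets were not analysed here, so a probe set outside the deleted part checks nothing about the labels. The per-array splicing index, the second test of exon usage, did not call the 3 probe sets used less (limma adjusted p = 0.0998, 0.0929 and 0.126). With the Y-linked signal as a covariate their diffSplice calls ended (adjusted p = 0.0626, 0.0815 and 0.17), at usage changes of -1.75, -1.70 and -1.52. The calls also ended without WT replicate 1, 2 or 3 or SRSF3HKO replicate 3 (for probe set 4625796, diffSplice adjusted p = 0.0665, 0.143, 0.0760 and 0.123). The count of 6 risen probe sets became 1 without WT replicate 2 and 3 without WT replicate 3. In 2 alternatives 2 Srsf3 probe sets were called lower, beside 6 higher without SRSF3HKO replicate 1 and 7 higher with array weights.

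**Figure D1:**
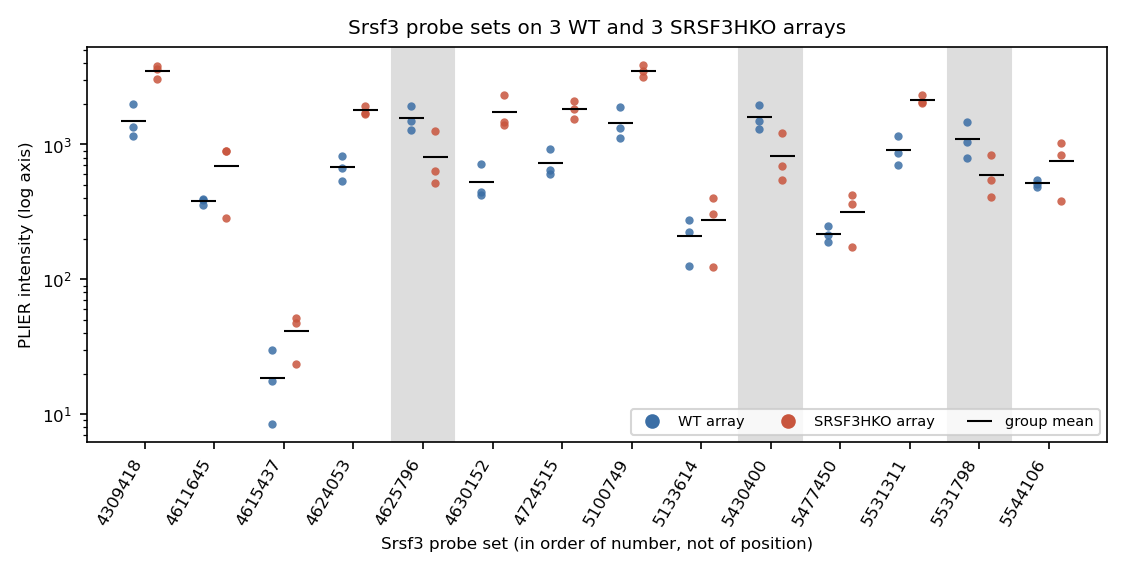
PLIER intensity (log axis) of each of the 14 Srsf3 probe sets, ordered by number, with 1 point per array and a bar at each group's mean; grey bands mark the 3 probe sets used less in SRSF3HKO. In those 3 the SRSF3HKO mean lies below the WT mean, and in the other 11 it lies above.

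The genes with the largest falls in SRSF3HKO livers included the carbonic anhydrase Car3 (log2 change -6.90 ± 0.97, limma adjusted p = 0.00586), the carboxylesterases Es31 (-6.61 ± 0.41), Ces3b (-6.06 ± 0.43) and Ces1f (-4.98 ± 0.35), and the glycosyltransferase Ugt3a1 (-5.07 ± 0.32). The organic anion transporter Slco1a1 went from a log2 value of 10.89 to below the detection floor, at least 46.4-fold lower (limma adjusted p = 0.000713). The genes with the highest rises included Cidec, which codes for a lipid droplet protein and was at least 40.4-fold higher (limma adjusted p = 8.67e-05), and Akr1c18, a hydroxysteroid dehydrogenase that was at least 28.7-fold higher (limma adjusted p = 0.000429). The estrogen sulfotransferase Sult1e1 was at least 24.0-fold higher and the fetal serum protein Afp at least 18-fold higher (limma adjusted p = 0.00286 and 0.0125), and the Afp call ended without WT replicate 1, 2 or 3 (limma adjusted p = 0.0525, 0.0704 and 0.0543).

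Of 11691 genes tested, 1393 changed, 803 higher and 590 lower in SRSF3HKO (limma, adjusted p under 0.05). The log2 change was at least 1 for 424 of the genes that rose, and 429 of those that fell were down by as much. The 3 arrays of a genotype did not overlap with the other 3 for 4170 genes (35.7%), against 10% by chance. Other high rises were those of the asparagine synthetase gene Asns (4.03 ± 0.36), the tetraspanin gene Cd63 (3.46 ± 0.25), Calml4 (3.45 ± 0.40), the tubulin gene Tuba8 (3.38 ± 0.37), the antiproliferative gene Btg2 (3.30 ± 0.33) and the retinol dehydrogenase gene Dhrs9 (3.18 ± 0.20). Bex1 was at least 7.98-fold and the fatty acid elongase gene Elovl7 at least 5.76-fold higher. Other large falls were those of Mup3 (-4.92 ± 0.73) and Mup4 (at least 28.5-fold lower), members of the major urinary protein family, whose near-identical copies the probe sets may not tell apart. Keg1 fell by 4.91 on the log2 scale, and Elovl3, another fatty acid elongase gene, was at least 16.8-fold lower. The steroid dehydrogenase gene Hsd3b5 and the fatty acid hydroxylase gene Cyp4a12a were at least 12.8-fold and 20.6-fold lower. In WT replicate 3, which lacked Y-linked signal, Elovl3, Hsd3b5 and Cyp4a12a had log2 values of 6.30, 5.64 and 7.14, against 10.87 or higher for Elovl3 and Cyp4a12a in the other WT arrays, and the Hsd3b5 call ended with the Y-linked covariate (limma adjusted p = 0.0635). Without WT replicate 2 the calls of Elovl3, Cyp4a12a, Hsd3b5 and Mup3 ended (limma adjusted p = 0.105, 0.107, 0.154 and 0.0534). Of 101 named genes, 49 lost their call without WT replicate 1, 49 without WT replicate 2 and 33 without WT replicate 3, all with the direction kept. The number of changed genes was 239, 271 and 432 without WT replicates 1, 2 and 3, 2171 without SRSF3HKO replicate 2, and 619 with the Y-linked signal as a covariate. The balance of directions was not stable, with 104 higher and 167 lower without WT replicate 2 and 126 higher and 170 lower at an adjusted p under 0.01. Among single probe sets, 14307 of 155942 changed, 7474 higher and 6833 lower, with 3026, 3781 and 5131 changed without WT replicates 1, 2 and 3, and 22127 without SRSF3HKO replicate 2. More of them were lower than higher with quantile normalization (7243 higher, 7553 lower), with median centring (6848 higher, 7805 lower) and without WT replicate 2 (1339 higher, 2442 lower).

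Cholesterol synthesis was the list with the largest share of changed members. Of its 21 measured genes 17 fell and none rose, from Hmgcs1 (log2 change -2.93 ± 0.24, limma adjusted p = 0.000827), which makes the precursor of mevalonate, to the late enzymes Tm7sf2 (-3.01 ± 0.30), Nsdhl (-2.69 ± 0.20) and Dhcr7 (-1.99 ± 0.24). Idi1, which isomerises isopentenyl diphosphate, fell by 3.12 ± 0.24 on the log2 scale. Adjusted over the list alone, 18 fell. The median log2 change was -1.73, with array medians of -1.77, -1.64 and -1.76 in SRSF3HKO (camera adjusted p = 7.31e-19; adjusted p = 0.132 with an estimated correlation). The mRNAs of the regulators Srebf2 (-0.12, adjusted p = 0.796) and Scap (-0.77, adjusted p = 0.0646) did not pass limma's test. Fatty acid synthesis genes were lower as well, with 8 of 20 down and 1 up, and with 13 down and 2 up adjusted over the list alone. Fads1 (-1.66 ± 0.19), Elovl5 (-1.56 ± 0.22), Acly (-1.92 ± 0.30) and Fasn (-2.47 ± 0.44) had the lowest adjusted p, though the Fasn call ended without WT replicate 1 (limma adjusted p = 0.0613), and Lpin2, whose product makes diacylglycerol, rose by 1.51. The median of this list was -1.29 (camera adjusted p = 5.85e-07; adjusted p = 0.346 with an estimated correlation).

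Glucose and glycogen metabolism lost 4 of 19 genes, with none higher. They were the pyruvate kinase gene Pklr (-2.70 ± 0.30), the glycogen phosphorylase gene Pygl (-1.44 ± 0.24), Pfkfb3 (-1.03 ± 0.24) and Irs1 (-0.91 ± 0.22), and adjusted over the list alone 10 fell and 1 rose. The list median was -0.89 (camera adjusted p = 1.10e-05; adjusted p = 0.346 with an estimated correlation), and the calls of Pfkfb3 and Irs1 ended with the Y-linked covariate (limma adjusted p = 0.0635 and 0.0881). Fatty acid oxidation and ketogenesis did not shift as a list (median 0.09 and mean -0.06, camera adjusted p = 0.320), with Acsl1 (-1.53 ± 0.22) and the receptor gene Ppara (-0.93 ± 0.24) down, Pdk4, an inhibitor of pyruvate oxidation, up by 2.42 ± 0.55, and the same counts, 2 down and 1 up, adjusted over the list alone. The Ppara and Pdk4 calls ended with the Y-linked covariate (limma adjusted p = 0.0891 and 0.0704). Without WT replicate 1 the calls of Pygl, Pfkfb3, Irs1, Ppara and Pdk4 ended (limma adjusted p = 0.0671, 0.128, 0.143, 0.140 and 0.0989).

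**Figure D2:**
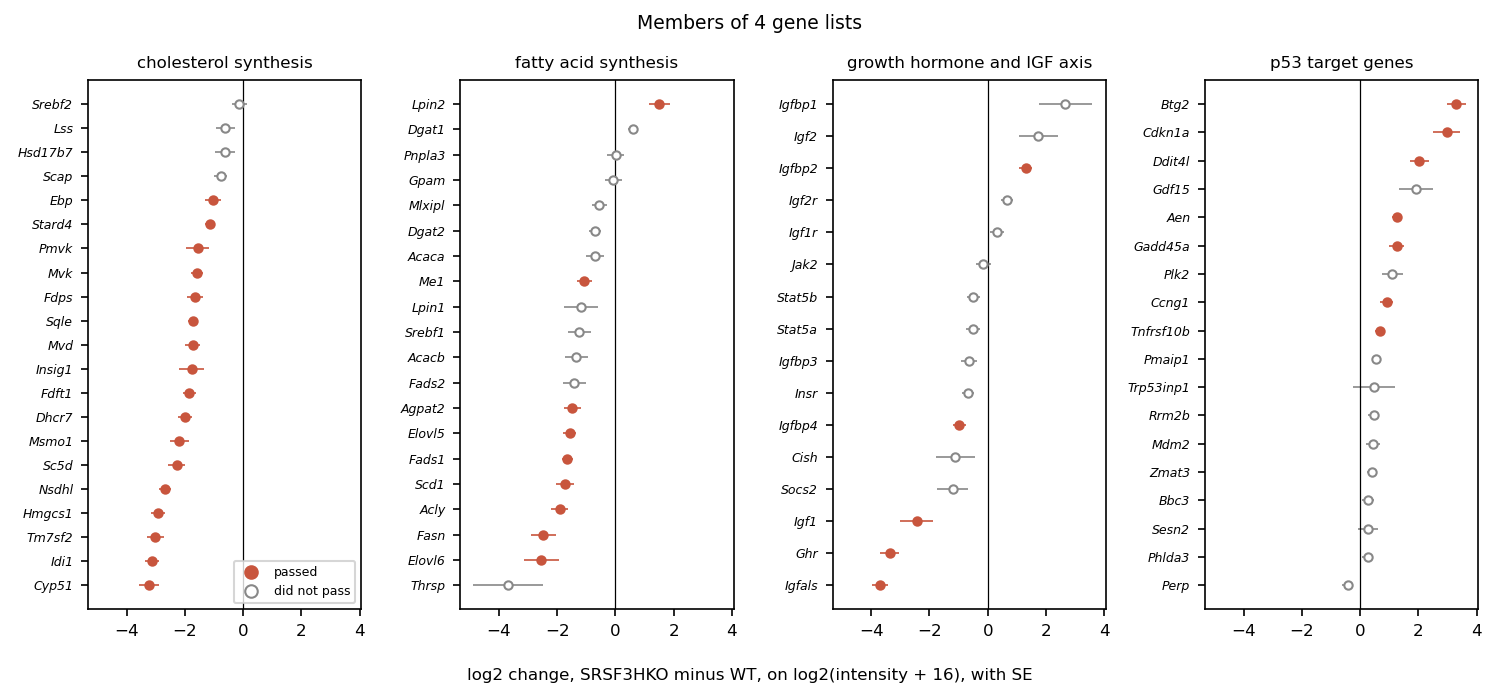
Log2 change (SRSF3HKO minus WT, log2(intensity + 16) scale) with SE for each measured member of 4 lists fixed beforehand; filled points passed limma's test over all genes. In the cholesterol synthesis list 17 of 21 members are filled and all lie to the left of 0, and in the p53 target list 7 of 18 are filled, to the right.

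The growth hormone and IGF axis fell at several steps. The growth hormone receptor gene Ghr fell by 3.37 ± 0.31 on the log2 scale, Igfals, which stabilises circulating IGF1, by 3.69 ± 0.28, and Igf1 by 2.44 ± 0.57, while the binding protein gene Igfbp2 rose by 1.30 ± 0.22 (limma adjusted p = 0.00126, 0.000532, 0.0321 and 0.0104). Of 16 measured genes 4 fell and 1 rose, and 5 fell and 3 rose adjusted over the list alone. The median was -0.58 (camera adjusted p = 0.0135; adjusted p = 0.346 with an estimated correlation). The list call ended without SRSF3HKO replicate 1 (median -0.44, camera adjusted p = 0.0533), and the Igf1 call ended with the Y-linked covariate (limma adjusted p = 0.0639) and, like that of Igfbp2, without WT replicate 2 (limma adjusted p = 0.129 and 0.0656). Genes with higher levels in male than in female liver followed the same direction. In this male-biased list 7 of 11 fell, among them Slco1a1 and Cyp7b1 (-3.51 ± 0.38), and adjusted over the list alone 7 fell and 1 rose. The median was -3.51, also with genes below the detection floor set at their bound (camera adjusted p = 4.41e-05; adjusted p = 0.409 with an estimated correlation). Y-linked signal was present on 2 WT arrays and 1 SRSF3HKO array, and within those the median was -3.91; within the 1 WT and 2 SRSF3HKO arrays without it the median was -1.29. In the female-biased list, 1 of 9 fell (Hao2, at least 11.3-fold lower) and 1 rose (Prom1, 2.36 ± 0.34), as adjusted over the list alone, with a median of -0.07 (camera adjusted p = 0.506).

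In the list of bile acid synthesis and transport, Cyp8b1 (-3.70 ± 0.40), Cyp7b1 and Hsd3b7 (-2.49 ± 0.33), enzymes of bile acid synthesis, fell with the transporter Slco1a1, and 7 of 20 genes fell in all. The 2 that rose were the canalicular transporter genes Abcc2 (0.98) and Abcg5 (0.83), and adjusted over the list alone 10 fell and 3 rose. The median was -0.81 (camera adjusted p = 9.72e-05; adjusted p = 0.346 with an estimated correlation). Xenobiotic metabolism genes fell in 6 of 23 cases, led by Cyp2j5 (-3.62 ± 0.46) and the aldehyde oxidase gene Aox3 (-2.30 ± 0.31), with 10 lower and 2 higher adjusted over the list alone and a median of -0.55 (camera adjusted p = 0.00314; adjusted p = 0.493 with an estimated correlation).

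Of 30 genes for mature hepatocyte proteins 27 had a negative log2 change and 8 fell, including Serpina1c (-1.57 ± 0.25), the complement gene C8a (-3.12 ± 0.53), the coagulation factor gene F11 (-1.66 ± 0.30) and the urea cycle gene Otc (-1.51 ± 0.35), and 9 fell adjusted over the list alone. The median was -0.27 (camera adjusted p = 7.86e-06; adjusted p = 0.346 with an estimated correlation). Albumin (Alb) had a log2 change of -0.02 ± 0.14 (limma adjusted p = 0.930), near the top of the intensity range. Among 19 hepatocyte transcription factors Cebpa (-1.48 ± 0.33), Rxra (-0.77 ± 0.19) and Ppara fell, 10 fell adjusted over the list alone, and no measured member had a positive log2 change. The median was -0.64 (camera adjusted p = 1.63e-05; adjusted p = 0.346 with an estimated correlation), and the calls of Otc, Cebpa and Rxra ended with the Y-linked covariate (limma adjusted p = 0.0704, 0.0696 and 0.0694). The 14 hepatocyte markers had a median of -0.17, with 3 lower in both adjustments, that is over all genes and adjusted over the list alone (camera adjusted p = 0.00477; adjusted p = 0.409 with an estimated correlation). The list call ended with quantile normalization (median -0.14, camera adjusted p = 0.0534). The hepatocyte marker Cyp2f2 (-3.45 ± 0.89) varied most, with log2 values of 8.08, 7.94 and 11.78 on the 3 SRSF3HKO arrays. Without WT replicate 1 the calls of Serpina1c, C8a, F11, Otc, Cebpa, Rxra and Cyp2f2 ended (limma adjusted p = 0.0560, 0.0631, 0.0768, 0.114, 0.105, 0.136 and 0.131). Serpina1c rests on 1 probe set.

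Fetal liver and liver tumour genes were higher. Gpc3 (2.21 ± 0.21), Aldoa (1.29 ± 0.17), Prom1, Peg3 (2.75) and Afp rose, 5 of 21 genes, 7 adjusted over the list alone, and none fell. The list median was 0.75, with array medians of 1.16, 0.88 and 0.26 (camera adjusted p = 1.44e-04; adjusted p = 0.346 with an estimated correlation). Among 18 p53 target genes 7 rose and none fell, with 11 higher adjusted over the list alone. They included Btg2, the cell cycle inhibitor gene Cdkn1a (2.97 ± 0.47, limma adjusted p = 0.00919), the nuclease gene Aen (1.27 ± 0.19) and Ddit4l (at least 2.89-fold higher), and the median was 0.61 (camera adjusted p = 4.31e-05; adjusted p = 0.132 with an estimated correlation). The Aen call ended without WT replicate 1, the Ddit4l call without WT replicate 2 (limma adjusted p = 0.0535 and 0.0551). In the cell cycle list 1 of 28 genes passed, also adjusted over the list alone. It was Ccne1, a driver of entry into S phase, which rose by 1.71 ± 0.25, whereas the list median was -0.44 (camera adjusted p = 0.0128; adjusted p = 0.773 with an estimated correlation). The cell cycle medians of the SRSF3HKO arrays were 0.50, -0.97 and -0.89, and the call ended without WT replicate 2, SRSF3HKO replicate 2 or SRSF3HKO replicate 3 (camera adjusted p = 0.0752, 0.371 and 0.195).

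Members of the stress lists moved in both directions. In the unfolded protein response list Asns, Atf3 (2.03 ± 0.24) and Ddit3 (1.24 ± 0.24) rose while the chaperone and foldase genes Pdia4 (-0.76 ± 0.17), Hyou1 and Calr and the sensor gene Ern1 fell. That made 3 up and 4 down of 24, 3 up and 8 down adjusted over the list alone, with a median of -0.15 and a mean of 0.09 (camera adjusted p = 0.231); the calls of Pdia4 and Ern1 ended with the Y-linked covariate (limma adjusted p = 0.0748 and 0.0817). Of 13 NRF2 antioxidant genes Hmox1 (2.10 ± 0.33), Nqo1 (2.16 ± 0.38) and Gsta2 (at least 2.91-fold higher) rose and Gclm and Me1 fell, with 5 up and 3 down adjusted over the list alone and a median of 0.51 (camera adjusted p = 0.164). Acute phase genes showed Crp (-3.07 ± 0.38), Itih4 (-1.44 ± 0.15) and Saa2 (at least 2.32-fold lower) down and the cytokine gene Il1b (2.35 ± 0.43) up among 23, with 3 down and 2 up adjusted over the list alone and a median of -0.12 (camera adjusted p = 0.164). For iron handling, Id1 (2.03 ± 0.21), the transferrin receptor gene Tfrc (1.36 ± 0.26) and the hepcidin gene Hamp (1.60 ± 0.38) rose, 3 of 13, with 4 up and 1 down adjusted over the list alone and a median of 0.03 (camera adjusted p = 0.665). Without WT replicate 2 the calls of Ddit3, Pdia4, Ern1, Hmox1, Nqo1, Gsta2, Gclm, Saa2, Il1b, Tfrc and Hamp ended (limma adjusted p = 0.0732, 0.113, 0.125, 0.0541, 0.0739, 0.111, 0.0758, 0.0563, 0.0714, 0.0842 and 0.0633). Gsta2, Saa2 and Hamp each rest on 1 probe set.

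Marker genes of other liver cells did not move together. Of 18 Kupffer cell and macrophage markers 4 rose, Gpnmb (at least 4.25-fold higher), Cd14 (at least 3.53-fold higher), Marco (2.78 ± 0.73) and Trem2 (0.78 ± 0.21), and 6 rose adjusted over the list alone. The list median was 0.91 (camera adjusted p = 0.00360; adjusted p = 0.686 with an estimated correlation), but the array medians were 2.46, 0.29 and 0.41 in SRSF3HKO replicates 1, 2 and 3. Without SRSF3HKO replicate 1 the median was 0.37 and the list call ended (camera adjusted p = 0.234), and with the Y-linked covariate the calls of Cd14, Marco and Trem2 ended (limma adjusted p = 0.0698, 0.0976 and 0.105). Over all alternatives in which they were tested, Trem2 lost its call in 15 of 19, Marco in 10 of 20, Cd14 in 7 of 19 and Gpnmb in 0 of 19. SRSF3HKO replicate 1 also held the highest lymphocyte, neutrophil and cell cycle medians, 0.85, 1.84 and 0.50. Endothelial markers had a median of -0.38, with Kdr (-0.87 ± 0.23) the 1 of 16 that fell and 0 adjusted over the list alone (camera adjusted p = 0.00360; adjusted p = 0.543 with an estimated correlation); the Kdr call ended with the Y-linked covariate (limma adjusted p = 0.0704). Stellate cell and fibroblast markers had a median of 0.02 (camera adjusted p = 0.808), with Pdgfra (1.57 ± 0.37) up and Ngfr (-0.83 ± 0.22) down of 16, and 3 up and 1 down adjusted over the list alone. Cholangiocyte markers (median 0.39, camera adjusted p = 0.253) and lymphocyte markers (median -0.13, camera adjusted p = 0.501) had no called member in either adjustment, and 4 neutrophil markers, too few for camera, had a median of 0.64 with 1 higher adjusted over the list alone. Of 6 erythroid markers Alas2, the first enzyme of heme synthesis in erythroid cells, fell by 2.35 ± 0.50, also adjusted over the list alone, with a list median of -0.36 (camera adjusted p = 0.0953). Pancreatic genes had a median of 0.17 with none called (camera adjusted p = 0.863). Of 6 adipose genes Cidec was higher and Car3 lower, also adjusted over the list alone, with a median of 0.14 (camera adjusted p = 0.704). Among 27 extracellular matrix genes Mmp12 (at least 3.09-fold higher) rose and Sparc (-1.17 ± 0.27) and Col3a1 (-1.41 ± 0.37) fell, in the same counts adjusted over the list alone, with a median of -0.20 (camera adjusted p = 0.0625). In the list of 19 epithelial-mesenchymal transition genes the epithelial cadherin gene Cdh1 rose by 1.52 ± 0.19 and the tight junction gene Cldn1 fell by 1.09 ± 0.27, with 2 up and 1 down adjusted over the list alone and a median of 0.27 (camera adjusted p = 0.504). Of the marker, matrix and transition genes named here, Cd14, Marco, Trem2, Kdr, Pdgfra, Ngfr, Alas2, Sparc, Col3a1 and Cldn1 lost their call without WT replicate 2 (limma adjusted p = 0.126, 0.154, 0.161, 0.140, 0.128, 0.0799, 0.0988, 0.106, 0.132 and 0.146).

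Of 31 lists tested, 15 passed with camera's preset correlation of 0.01, 12 lower and 3 higher. With an estimated correlation 0 passed with camera, 3 had an unadjusted p under 0.05, and limma's directional fry called 11. These 11 include iron handling and adipose genes (fry adjusted p = 0.030 and 0.0136), which camera did not call. Fry did not call xenobiotic metabolism, hepatocyte transcription factors, cell cycle, male-biased genes, macrophage markers or endothelial markers (fry adjusted p = 0.187, 0.0663, 0.657, 0.0912, 0.232 and 0.202). A filter at the median ended the camera calls of cell cycle and macrophage markers (adjusted p = 0.285 and 0.0738). Camera also called 15 lists when WT replicates 1 and 3 and SRSF3HKO replicate 3 were set against the other arrays, so the number of lists called did not set the genotypes apart from that split. Single lists did not do so by their preset p either, since each of the 15 also passed in 2 to 9 of the 9 other splits. Another split gave a larger median for macrophage markers (0.911 in size against 0.907), xenobiotic metabolism (0.606 against 0.550) and endothelial markers (0.437 against 0.385). Macrophage markers passed in 9 and cholesterol synthesis in 8, the latter with a median of at most 0.81 in size against 1.73. The cell cycle list passed in 6, with a larger median in 3 and an adjusted p down to 6.98e-27.

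**Figure D3:**
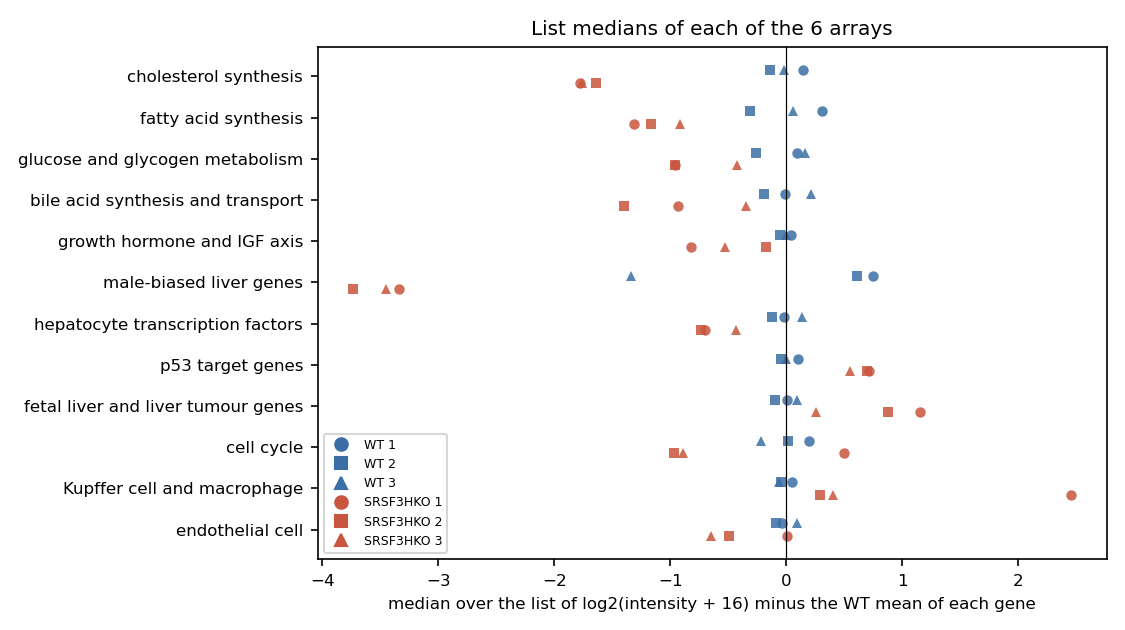
Median, over the genes of each of 12 lists, of log2(intensity + 16) minus the gene's WT mean; each of the 6 arrays has 1 symbol, WT in blue and SRSF3HKO in red. Cholesterol synthesis lies between -1.77 and -1.64 on the 3 SRSF3HKO arrays, whereas the macrophage median of SRSF3HKO replicate 1, at 2.46, stands apart from 0.29 and 0.41 on the others.

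The other members of the SR protein family did not pass at gene level. None of 11 measured SR genes was called, either over all genes or adjusted over the list alone. The values nearest the threshold were those of Srsf11 (0.89 ± 0.24, limma adjusted p = 0.0515) and Srsf5 (1.31 ± 0.51, limma adjusted p = 0.133), and the list median was 0.33 (camera adjusted p = 0.506). The remaining log2 changes ran from -0.68 for Srsf2 to 0.43 for Srsf10. Of 31 other splicing factors Hnrnpa2b1 (0.74 ± 0.19) and Mbnl2 (0.92 ± 0.24) rose and the epithelial factor Esrp2 (-0.80 ± 0.20) fell, in the same counts adjusted over the list alone, with a median of 0.20 (camera adjusted p = 0.259). These 3 calls ended with the Y-linked covariate (limma adjusted p = 0.110, 0.105 and 0.0930) and without WT replicate 2 (limma adjusted p = 0.154, 0.156 and 0.110).

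By diffSplice, single probe sets of Fn1, Srpk1 and Atp9b changed relative to the rest of their gene. The per-array splicing index did not call them (limma adjusted p = 0.297 for Fn1 probe set 5430598, 0.0800 for Srpk1 and 0.0664 for Atp9b). The SE of a usage change comes from a spread pooled over all probe sets of the gene, not from the probe set alone. In Fn1, the fibronectin gene, 2 of 54 tested probe sets were used more in SRSF3HKO: probe set 5430598 went from an intensity of 89.2 ± 26.2 to 293 ± 234 (SD, n = 3) while the gene's median level had a log2 change of -0.47, a usage change of 1.78 ± 0.20 (diffSplice adjusted p = 8.06e-12). Tested by itself, probe set 5430598 had a log2 change of 1.33 ± 0.47 (limma adjusted p = 0.114). Probe set 5201971 had a usage change of 1.21. In the kinase gene Srpk1, whose product phosphorylates SR proteins, probe set 4567928 went from 283 ± 56.0 to 78.5 ± 25.1 at a gene-level log2 change of 0.34 (usage change -2.13 ± 0.19, diffSplice adjusted p = 2.57e-12). The lowest adjusted p was that of probe set 4507343 of Atp9b, a flippase gene, which went from 401 ± 78.2 to 38.1 ± 18.8 (usage change -2.92 ± 0.24, diffSplice adjusted p = 2.99e-18).

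Of 131600 probe sets in 10403 genes, diffSplice called 835 in 665 genes, 371 used more and 464 used less, and its Simes test called 616 genes. Of the 665 genes, 243 also changed at gene level. Probe sets used more included those of Aplp2 (1.43 ± 0.16) and Asap3 (2.64 ± 0.31). The called probe sets of the laminin gene Lamc3, the nucleoporin gene Seh1l and Hspa12a had WT means below the probe set floor of 5.67, so only their intensities are given, 26.1 ± 11.9 and 211 ± 36.6 for Lamc3, 33.6 ± 11.5 and 161 ± 74.7 for Seh1l, and 23.7 ± 14.5 and 308 ± 96.1 for Hspa12a. The probe set of complement C3 was used less (-0.72 ± 0.09), going from 4767 ± 399 to 2160 ± 292. In Hgfac and Ces1f, which fell at gene level (log2 change -2.34 and -4.98), the called probe sets were dim, with intensities of 40.5 ± 14.1 (WT) and 64.5 ± 39.1 (SRSF3HKO) for Hgfac, at a usage change of 2.47, and of 55.3 ± 4.34 and 25.1 ± 14.3 for Ces1f, the latter below the floor. The Pzp probe set (usage change 4.91 ± 0.47) had a WT intensity of 1481 ± 2555, an SD above its mean. Among the fixed genes, Hmgcs1 had 2 of 13 probe sets called, the first at 317 ± 156 in WT and 292 ± 52.6 in SRSF3HKO while the gene fell (usage change 2.45 ± 0.29, diffSplice adjusted p = 6.10e-08). Dhcr7 had 1 of 10, at 1303 ± 169 and 1147 ± 71.1 (2.36 ± 0.33), and Numb had 1 of 13, which went from 826 ± 64.3 to 256 ± 55.2 (-1.17 ± 0.23, diffSplice adjusted p = 0.00182). No probe set was called in Arhgef10l (lowest diffSplice adjusted p = 0.0519), Nfib (0.0630), Srsf2, Srsf7, Slk, Ern1, Exoc7, Pkm, Csnk1d, Scap, Ptbp1 or Insr. At gene level 5 of the 17 fixed genes fell, Hmgcs1, Dhcr7, Ern1, Nfib (-1.12 ± 0.18) and Arhgef10l (-0.79 ± 0.20), 10 fell adjusted over the list alone, and the median was -0.68. The Nfib and Arhgef10l calls ended without WT replicate 1 (limma adjusted p = 0.0630 and 0.133).

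The per-array splicing index, tested with limma, called 16 probe sets, 12 of them shared with diffSplice. Asap3 was the only one of the 12 genes with the lowest diffSplice adjusted p that the index also called. The other shared calls, named here after their values were seen, were in Cluap1, Comtd1, Cyp4f16, Dnttip1, Epb41l5, Id1, Lipc, Pnkd and Sri. In Sri a probe set went from 39.3 to 487 (usage change 3.65), and in Epb41l5 a probe set went from 41.7 to 412 (usage change 2.60). All 12 shared calls ran against the gene-level log2 change. Id1, Cluap1 and Dnttip1 rose at gene level (log2 change 2.03, 2.04 and 1.32). Their called probe sets did not pass by themselves (limma adjusted p = 0.893, 0.350 and 0.274), whereas those of the other genes did. In simulated data with known changes, 33.7% of diffSplice calls were false with spreads shrunk across probe sets and 59.0% with the measured spreads, against 2.70% and 3.00% of calls made by both tests. The simulation moved all probe sets of a changed gene alike. Its shares therefore leave out probe sets that follow their gene's change less than others. The diffSplice count was 367, 349 and 481 without WT replicates 1, 2 and 3, 2049 without SRSF3HKO replicate 2, and 462 with the Y-linked covariate.

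**Figure D4:**
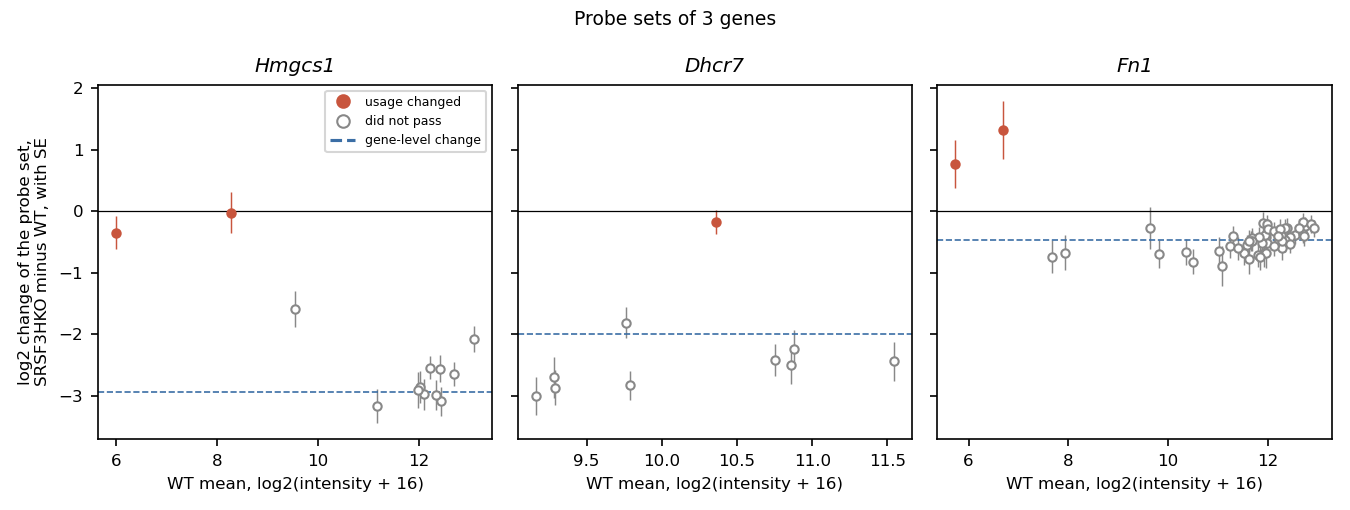
Log2 change of each tested probe set (SRSF3HKO minus WT, with SE) against its WT mean log2(intensity + 16) in Hmgcs1, Dhcr7 and Fn1; filled points had a changed usage by diffSplice and the dashed line is the gene-level change. The 2 called Fn1 probe sets lie above 0 at a WT mean of 5.74 and 6.68, dimmer than the other Fn1 probe sets.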

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

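The Y-linked covariate was chosen only after the arrays were seen, and all other alternatives were set before. The 1393 changed genes became 2156 with array weights, 296 at an adjusted p under 0.01 (a stricter threshold), 619 with the Y-linked covariate, and 239 to 2171 when 1 array was left out. The 14307 changed probe sets became 23530, 3344, 6259 and 3026 to 22127 under the same alternatives. The 6 risen Srsf3 probe sets became 1 at an adjusted p under 0.01 and 1 to 9 when 1 array was left out. The 835 probe sets with changed usage became 1290 with no filter, 511 with a filter at the median, 1924 with array weights, 403 at an adjusted p under 0.01, 16 with the splicing index, 317 in genes changed under 1.5-fold (fewer genes), 462 with the covariate, and 349 to 2049 when 1 array was left out. The 15 lists called became 0 with camera at an estimated correlation, where 3 had an unadjusted p under 0.05, 28 with fry for mixed directions, and 14 to 16 when 1 array was left out; directional fry called 11. The gene-level change of Srsf3, 0.26, reversed to -0.022 without SRSF3HKO replicate 1, and ran from there to 0.58 (without SRSF3HKO replicate 2) when 1 array was left out; it was 0.56 with the mean and 0.81 with median polish over probe sets. Apart from the stricter threshold and the smaller set of genes, the cause was not tested. Leaving out an array did not always lower the counts, which rose to 2171 genes, 22127 probe sets and 2049 usage calls without SRSF3HKO replicate 2. Across genes that array correlated with SRSF3HKO replicates 1 and 3 at Pearson's r of 0.940 and 0.953, and those 2 with each other at 0.965. All counts stayed within 1.5 times under pseudocounts of 1 and 64, quantile normalization, median centring and robust eBayes, as did those of genes and lists with the mean or median polish over probe sets, and all but exon usage under eBayes without trend, which does not apply to diffSplice. Of 101 named genes, 49 kept direction and side of the threshold under every alternative in which they were tested, as did 1 of 18 named probe sets for usage (Asap3) and 0 of 15 lists, and 92 of the genes were tested under all of them. Lost gene calls kept their direction. The share of changed genes that were higher was 57.7%, against 52.4% with quantile normalization 51.2% with median centring, 42.6% at an adjusted p under 0.01 and 38.4% to 64.3% when 1 array was left out; for probe sets 52.2% became 49.0%, 46.7%, 38.3% and 35.4% to 54.5%, so neither direction prevailed throughout. No paired analysis was possible because nothing in the labels pairs the samples and replicate numbers follow the order of the samples. Signal over background limited dim genes, whose folds are understated or lower bounds.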

Other observations

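The tests of unequal sexes, of the hepatocyte share and of the size of the macrophage shift were chosen only after the results they test were seen. Beyond Asns, Atf3 and Ddit3, other targets of the transcription factor ATF4 were examined with 25 genes not used before. The tRNA synthetase genes Gars (log2 change 1.13) and Sars (1.04), Ddit4 (2.18) and Vldlr (1.94) rose and Atf5 (-1.59) fell. Of 15 further chaperone and secretory genes Derl3 (at least 3.70-fold lower) and Pdia3 (-0.71) fell and none rose. The medians were 0.46 and -0.14 (permutation p = 0.014 over genes), short of the median of 0.5 set beforehand for an ATF4-type response, so this reading stays open. The permutation treats genes as independent, so its p does not measure the spread between mice.

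Imprinted genes outside the fixed lists did not rise as a group, with a median of 0.13 over 13 genes, against 0.08 over all genes tested. Of these 13 genes 2, Impact (1.73) and Phlda2 (at least 1.81-fold higher), rose and 0 fell. Peg3 and H19 were not among the 13. The median argues against a general rise of these 13 genes only. H19 had a log2 change of 4.06 (limma adjusted p = 0.0640). The mRNA of Zbtb20, a repressor of Afp, changed by -0.50 (95% interval -1.11 to 0.12, limma adjusted p = 0.263) and that of Zhx2 by -0.17 (limma adjusted p = 0.686), which leaves open whether loss of a repressor could account for the rise of Afp and Gpc3.

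Of the 10 splits of the 6 arrays into 3 and 3, the genotypes gave 1393 changed genes against at most 1 for any other, 14307 probe sets against 35 (the split by Y-linked signal), 835 usage calls against 64 and 6 Srsf3 probe sets against 0. In each of these 4 results only 1 split, the real one, had as many calls. For lists 2 of 10 splits had as many, 15 and 15. Because 10 splits cannot give a share under 0.1, chance is neither excluded nor shown as the source of the difference.

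The rise of macrophage markers could reflect a lower share of hepatocyte RNA, which would raise markers of all other cells alike. Macrophage markers exceeded endothelial markers by 1.29 (medians 0.91 and -0.38, permutation p = 0.00013 over genes). The permutation treats genes as independent, but their estimated correlation was 0.735 in the macrophage list and 0.437 in the endothelial list. Its p therefore does not measure the spread between mice and decides nothing about the hepatocyte share. The endothelial medians of the SRSF3HKO arrays, 0.012, -0.493 and -0.65, did not exceed the highest WT median, 0.096, so the lists did not rise alike on these arrays. In 3 of 3 SRSF3HKO arrays the median, 2.46, 0.29 and 0.41, lay above the highest WT median of 0.05, so a single array does not account for the direction. The size does depend on 1 array: without SRSF3HKO replicate 1 the median was 0.37 rather than 0.91 (camera adjusted p = 0.234). It was still 0.95 above the endothelial markers (permutation p = 0.0017 over genes, with the same limit). More macrophages and a changed state of the same cells may both be behind it, and cell counts were not analysed here.

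The lower male-biased genes could reflect unequal sexes, since Y-linked signal was present on 2 WT arrays and 1 SRSF3HKO array. With that signal as a covariate the median was -3.26 rather than -3.51 (camera adjusted p = 4.4e-05 at the preset correlation), and 6 of the 7 genes that fell kept their limma call. For each gene this fit averages the contrasts within arrays with and within arrays without Y-linked signal, so it is not evidence apart from them. It also assumes the same difference between the sexes in both genotypes. For Elovl3 that difference was large in WT (11.05 and 10.93 against 6.30), while all SRSF3HKO values lay below the floor. Even without the covariate the list itself did not pass with an estimated correlation (adjusted p = 0.409) or directional fry (adjusted p = 0.0912). The median was -3.91 within arrays with Y-linked signal and -1.29 within arrays without it, but each of these sets 1 array against 2 and excludes nothing by itself, so how much of the size comes from sex stays open.

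Calls of exon usage might arise where dim probe sets follow their gene's change less than bright ones. Among genes changed at least 1.5-fold, 78.2% of 435 calls (95% interval 74.0% to 82.0%) ran against the gene's change, as this technical explanation predicts. In genes changed under 1.5-fold it predicts few calls, but 400 probe sets were called there, 0.415% against 1.24% in genes changed more. Any other split gave at most 63 calls in these genes. A gene's change is here the median over its probe sets, so single probe sets can change more than it. Srsf3 is in this class, with a gene-level log2 change of 0.26 and 6 probe sets up by 1.25 to 1.68. The 400 calls therefore do not exclude the technical explanation. A technical effect that follows genotype would also shrink when genotypes are mixed, so the splits cannot tell it from splicing. When only the genes changed under 1.5-fold were tested 317 passed, and the splicing index called 16 in all genes. On simulated data 33.7% or 59.0% of diffSplice calls were false, depending on the spread, shares that also depend on the number of changes put in. The simulation moved all probe sets of a changed gene alike, so it did not include this technical effect. Splicing changes from the loss of SRSF3 could account for a part of the 400, of unknown size, since the probe sets were not matched to exons.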
